A study of Mus musculus with 11 samples.

How the data were processed

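Chromatin was profiled by CUT&Tag, in which an antibody tethers a transposase that inserts sequencing adapters next to the bound protein or histone mark. The cells were endocrine cells of the mouse pancreas, sorted for the tdTomato reporter that Neurod1-cre switches on. H3K27ac, a mark of active promoters and enhancers, and H3K27me3, the mark placed by Polycomb at silenced genes, were measured at postnatal day 9 in Control (Isl1loxP/+;Neurod1-cre, heterozygous) and Isl1CKO (Isl1loxP/loxP;Neurod1-cre) mice. Each genotype and mark had 2 libraries. Per the series design, these came from independent pools of 3 to 4 pancreases and about 20000 cells each. Binding of the transcription factor ISL1 was measured in Control cells at E14.5 (2 libraries, given as a single pooled column) and at P9 (1 library). Groups were taken from the sample labels.

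Per the labels, reads were aligned with Bowtie2 2.3.5.1 to GRCm39, and Picard 2.27.4, MACS2 2.2.6, ChIPseeker 1.38.0 and edgeR 4.0.16 were also used. The authors deposited raw counts per region for each library of both histone marks, together with region coordinates and annotation. Beside these counts stood the authors' log2 fold change of Isl1CKO over Control, their log2 mean abundance, a likelihood ratio score for each region, and a p value with its adjusted p value. The deposited ISL1 file has other values, whole numbers per promoter window for each stage, whose unit its header does not state. These numbers are called ISL1 values here. Every deposited histone region had at least 50 counts over the 4 libraries. The H3K27ac file listed 31587 regions, of which 108 were repeats, and the H3K27me3 file listed 20176, of which 90 were repeats. The columns of per-sample values not used numbered 0.

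The chromosome numbers of the histone files followed the alphabetical order of chromosome names. For regions whose gene was also in the ISL1 file, 7.48% of H3K27ac and 9.25% of H3K27me3 chromosome labels matched as written. After relabelling by that order, 100% matched for 18449 and 10277 regions respectively. The same check against the reference gene table gave 100% for 24801 and 14921 regions. All coordinates printed here carry the corrected labels on GRCm39, the build named in the labels.

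Counts were analysed with edgeR 4.0.16 in R 4.3.3. Regions were filtered with filterByExpr by genotype, which left 30036 H3K27ac regions (1443 removed) and 19434 H3K27me3 regions (652 removed). Libraries were scaled with TMM factors, and genotypes were compared with the quasi-likelihood test for 2 against 2 libraries. P values were adjusted by Benjamini-Hochberg over all tested regions of a mark, and a region was called at an adjusted p below 0.05. Values per group are TMM-scaled CPM over the counts in regions, given as mean ± SD with n = 2 unless stated. Log2 fold changes are of Isl1CKO over Control with the standard error of the fit. Where a group had 0 counts over its libraries, the fold of summed counts is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, a ratio of summed counts is given with its exact 95% counting interval. A count of 0 in a single library allowed a level of up to 1.64 to 4.56 CPM for H3K27ac and 1.28 to 2.64 for H3K27me3. Intervals and floors cover counting error only.

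The 19 gene lists were beta, alpha, delta, and PP and epsilon cell identity genes, islet transcription factors, endocrine progenitor genes, hormone secretion machinery, genes silenced in beta cells (beta-disallowed genes) and gut endocrine genes. They also held Polycomb-regulated developmental genes, neuronal, cell cycle and stress response genes, and markers of acinar, ductal, endothelial, mesenchymal, immune and glial cells. Each gene was represented by its promoter region with the highest mean count, or its highest region where it had no promoter region. Lists were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted by Benjamini-Hochberg over the lists of a mark. Named regions were, per mark and direction, the 4 with the smallest unadjusted p in which both Isl1CKO libraries lay on the same side of both Control libraries, a number that applied because fewer than 3 were called. Regions of Isl1, of the islet genes Ins1, Ins2, Gcg, Sst, Ppy, Mafa, Pdx1, Nkx6-1, Slc2a2 and Ucn3, and 2 members per list were also named, along with the ISL1 windows of the same genes and the 8 windows with the highest ISL1 value. Of the genes this rule selects, 2 are not reported here. The lists, this rule, the tests and most alternatives were chosen before the data were examined.

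The 2 marks were compared across genes with Spearman and Pearson correlations of promoter log2 fold changes, each with 10000 permutations, and with Fisher's exact test on called genes. ISL1 windows were counted at a value of at least 1. ISL1 windows of the gene lists were compared with 10000 random lists. These were matched on the class of promoter H3K27ac (none or tertile), the presence of a promoter H3K27me3 region, and a window wider than 6000 bp or not. The p values from these random lists are called permutation p values here. The overlap of ISL1 windows with histone regions (at least 1 bp) was tested with Fisher's exact test, two-sided, within tertiles of mean count and of width as well. Because no region was called, the overlap used regions at an unadjusted p below 0.05. The list and overlap tests of ISL1 were chosen in that form after seeing the data.

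Alternatives were DESeq2 1.42.0, its size factors within edgeR, library totals alone, no filter, a replicate block, leaving out each library in turn, promoter regions alone, an absolute log2 fold change of at least 1, and the authors' own table. Chosen after seeing the data were the library sizes and the preset dispersion implied by the authors' table, a loess correction of each library against abundance (span 0.3), counts summed per gene, the filter applied again without a library, and thinning of the ISL1 values. DESeq2 used a local dispersion fit. Library sizes and a single preset dispersion were fitted to the deposited columns of the authors' table, which gave a dispersion of 0.04. A likelihood ratio test with both the fitted sizes and this dispersion gave the same call for 99.98% of H3K27ac and 99.99% of H3K27me3 regions.

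The tests were tried on simulated counts with the observed dispersions, with 50 regions changed at each fold. The quasi-likelihood test recovered 18% of 4-fold and 72% of 16-fold changes for H3K27ac, and 28% and 48% for H3K27me3, with 1 unchanged region called in each mark. At 2-fold it recovered 0% and 2%. With the preset dispersion, the likelihood ratio test called 14.5% of unchanged H3K27ac regions and 25.5% of unchanged H3K27me3 regions. For a simulated list shifted 2-fold, camera gave an adjusted p of 0.00107 for H3K27ac and 0.0571 for H3K27me3. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for joins, exact tests and plots.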

Results

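H3K27ac and H3K27me3 were measured in sorted endocrine cells of P9 mice, in 2 Control and 2 Isl1CKO libraries per mark, and ISL1 binding was measured in Control cells at E14.5 and P9. The H3K27ac libraries held 1307049 and 1815511 counts in regions for Control and 681047 and 1441926 for Isl1CKO. The H3K27me3 libraries held 1202276 and 1750706 for Control and 2276887 and 2260039 for Isl1CKO. H3K27ac was listed at 31479 regions with a median width of 999 bp, 47.6% of them promoters, next to 16450 genes. H3K27me3 was listed at 20086 regions with a median width of 1294 bp, 32.9% of them promoters and 32.8% distal, next to 8088 genes. Regions of at least 5000 bp numbered 86 for H3K27ac and 1581 for H3K27me3. The H3K27ac library of Control replicate 2 stood apart from the other 3. It correlated with them at r = 0.430 to 0.475 across regions, against 0.737 to 0.774 among the others, and 1194 regions had over 70% of their scaled signal in it, against 18, 7 and 34 in the others. The H3K27me3 libraries correlated at r = 0.690 to 0.824.

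The first comparison asked where the active mark H3K27ac differed between Isl1CKO and Control endocrine cells at P9. The deleted gene itself was read first. Isl1 (ENSMUSG00000042258), which encodes the LIM-homeodomain factor under study, had 7 H3K27ac regions with log2 fold changes from -2.05 to 0.47. Its promoter region (chromosome 13, 116445217 to 116447343) held 82 and 78 counts in Control and 30 and 65 in Isl1CKO, or 53.0 ± 14.53 and 45.7 ± 0.0241 CPM (SD, n = 2). That is a log2 fold change of -0.21 (SE 0.48), positive at 0.40 with the library sizes implied by the authors' table and at 0.09 without Control replicate 1, and -0.48 without Control replicate 2. An Isl1 intron region (chromosome 13, 116440265 to 116441140) measured 20.6 ± 1.86 in Control and 5.21 ± 3.39 in Isl1CKO (SD, n = 2), with a log2 fold change of -2.05 (SE 1.03). The labels do not say which exon is removed, so these values do not check the deletion.

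H3K27ac next to several genes of mature beta cells measured lower in Isl1CKO, without passing the test. Mafa (ENSMUSG00000047591), a transcription factor of beta cell maturation, measured 38.5 ± 12.98 CPM in Control and 12.2 ± 4.30 in Isl1CKO (SD, n = 2) at its promoter (chromosome 15, 75619911 to 75620704), a log2 fold change of -1.70 (SE 0.69). A distal Mafa region (chromosome 15, 75612792 to 75613594) held 21 and 36 counts in Control and 1 and 0 in Isl1CKO, a ratio of 0.0263 with a counting interval of 0.000655 to 0.153. Ucn3, a peptide hormone of mature beta cells, had 24 and 38 counts in Control and 0 and 0 in Isl1CKO at a region within 1 to 2 kb of its start (chromosome 13, 3992584 to 3993401), at least 13.8-fold lower. At the Ucn3 promoter itself (chromosome 13, 3993538 to 3994405) the log2 fold change was -2.13 (SE 1.23), and -1.33 without Isl1CKO replicate 1. Glp1r, the receptor for the incretin GLP-1, measured 109.7 ± 28.5 in Control and 48.5 ± 23.9 in Isl1CKO (SD, n = 2) at its promoter (chromosome 17, 31119886 to 31123517), a log2 fold change of -1.22 (SE 0.44) that was -0.76 without Isl1CKO replicate 2. Abcc8, the sulfonylurea receptor subunit of the beta cell potassium channel, measured 91.5 ± 6.99 and 26.99 ± 1.59 (SD, n = 2) 1 to 2 kb from its start (chromosome 7, 45825372 to 45828319), a log2 fold change of -1.75 (SE 0.45). The edgeR adjusted p was 0.838 for Abcc8 and the Ucn3 region at 1 to 2 kb, 0.886 for the Ucn3 promoter, 0.850 for the Mafa promoter, and 0.846 for the distal Mafa region and Glp1r.

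Nkx6-1, Pdx1 and Slc2a2 showed smaller differences between the genotypes at the promoter region with the highest mean count of each. The other H3K27ac regions of Nkx6-1 had log2 fold changes from -0.67 to 0.33, and those of Slc2a2 from -0.97 to 0.39. The other Pdx1 region stood at -0.90 (SE 0.59), with both Isl1CKO libraries below both Control libraries. The promoter of Nkx6-1, a homeobox factor of beta cells, measured 109 ± 6.21 CPM in Control and 132 ± 14.1 in Isl1CKO (SD, n = 2). The promoter of Pdx1, a homeobox factor of pancreas and beta cells, measured 88.0 ± 1.11 and 88.6 ± 44.7 (SD, n = 2), a log2 fold change of -0.02 (SE 0.41) that was 0.84 with the authors' implied sizes, -0.63 without Isl1CKO replicate 1 and 0.44 without Isl1CKO replicate 2. The promoter of Slc2a2, the glucose transporter GLUT2, measured 45.0 ± 4.63 and 33.0 ± 4.95 (SD, n = 2), with a log2 fold change of -0.46 (SE 0.53) that was 0.26 with those sizes. Among hormone genes, Ins1 had a log2 fold change of -1.04 (SE 1.10), which was 0.45 without Control replicate 2 and -1.73 without Control replicate 1. Ppy, which encodes pancreatic polypeptide, had one of -1.22 (SE 0.86), which was -0.55 without Control replicate 2 and -3.05 without Isl1CKO replicate 2. No H3K27ac region was listed for Ins2, Gcg or Sst.

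The regions with the smallest p were next to genes outside the endocrine lists. Prr35 measured 28.6 ± 3.23 CPM in Control and 127 ± 16.4 in Isl1CKO (SD, n = 2) at a region upstream of the gene, at -10605 bp from its start (chromosome 17, 26182144 to 26184504), a log2 fold change of 2.15 (SE 0.40) with an edgeR adjusted p of 0.734. C1qtnf5, a secreted protein of the C1q family, had 0 and 0 counts in Control and 10 and 56 in Isl1CKO at its promoter (chromosome 9, 44016856 to 44017841), at least 33.0-fold higher. The log2 fold change was 3.39 (SE 0.78) at a region upstream of Pla2g2c, a secreted phospholipase, at -3213 bp from its start (chromosome 4, 138447771 to 138448890). It was 2.59 (SE 0.60) at Il17re, an interleukin receptor subunit (chromosome 6, 113435326 to 113436515). Lower values stood at Zfp94, a zinc finger gene (chromosome 7, 24015660 to 24016469), with 46.0 ± 20.3 in Control and 2.22 ± 1.16 in Isl1CKO (SD, n = 2). Cdh23, a cadherin of hair cell tip links, had 24 and 64 counts in Control and 0 and 0 in Isl1CKO in an intron (chromosome 10, 60430706 to 60431442), at least 19.6-fold lower. At the promoter of Cbs, an enzyme of cysteine synthesis (chromosome 17, 31855324 to 31856517), the log2 fold change was -2.23 (SE 0.53), and -1.30 without Control replicate 2. A distal region near the ribosomal protein gene Rpl29 (chromosome 9, 106287465 to 106288731) held 36 and 71 counts in Control and 0 and 3 in Isl1CKO, a ratio of 0.0420 with a counting interval of 0.00854 to 0.126.

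By list, no group of genes passed camera for H3K27ac. The median of all regions was -0.03 with TMM and 0.61 with the authors' implied sizes, so a list median less negative than this shift would turn positive with those sizes. Other settings changed the direction that camera gave in 11 of the 19 lists. Of 18 measured beta identity genes, 15 measured lower and 3 higher, with a median log2 fold change of -0.34 (camera adjusted p = 0.213, and 0.887 with an estimated correlation). In 5 of these genes both Isl1CKO libraries lay below both Control libraries, and in 2 both lay above. In the authors' table, 3 of these genes were called lower and 3 higher. Of 11 gut endocrine genes, 8 measured lower, with a median of -0.61 and the same camera adjusted p of 0.213. Lmx1a, a LIM-homeodomain gene on that list, stood at -2.96 (SE 0.99), or -1.95 without Control replicate 2, and Pyy, the peptide YY gene, at -1.53 (SE 0.67), or -0.48 without Control replicate 1. Of 5 PP and epsilon genes, 4 measured lower, with a median of -1.35 (camera adjusted p = 0.183). With an estimated correlation, the adjusted p was 0.887 for this list and the gut endocrine list. These lists share genes and are not separate evidence: Ucn3 is also a beta identity gene on the gut endocrine list. Pyy is on both the gut endocrine and the PP and epsilon lists. Frzb, a secreted Wnt antagonist among the PP and epsilon genes, stood at -1.35 (SE 0.55), or -0.71 without Control replicate 2. Without that library, the medians were -0.23 for beta identity, -0.40 for gut endocrine and -0.71 for PP and epsilon genes. The camera adjusted p was 0.593 for the 5 delta genes (4 lower, median -0.72), which include the ghrelin receptor gene Ghsr at -3.22 (SE 1.10) and the calcium channel gene Cacna2d3 at 2.35 (SE 0.80). The 13 alpha genes (5 lower, 8 higher) had a median of 0.06, the 21 islet transcription factors (9 lower, 12 higher) one of 0.10, and the 16 endocrine progenitor genes (6 lower, 10 higher) one of 0.19. The 28 genes of hormone secretion (12 lower, 16 higher) had a median of 0.02, although camera pointed down. The 17 beta-disallowed genes had a median of -0.15, the 14 cell cycle genes -0.20, the 10 stress genes 0.04, the 10 neuronal genes 0.01 and the 6 Polycomb genes -0.52. Among markers of other cell types, the medians were 0.06 for 5 acinar, -0.05 for 9 ductal, -0.85 for 5 endothelial, 0.63 for 5 mesenchymal, 0.50 for 5 immune and -0.03 for 4 glial genes. Without Control replicate 2, the medians were 0.30 for endothelial, -0.24 for immune and -0.05 for Polycomb genes, and without Isl1CKO replicate 2 the delta median was -0.24. For the stress, neuronal and acinar lists, camera pointed down while the median was positive. Adjusted over the list alone, 5 genes in 4 lists passed: Cpa1, an acinar carboxypeptidase (-1.98, SE 0.52), Cacna2d3, Ghsr, Abcc8 and the neural gene Olig3 (-2.63, SE 0.87, or -1.52 without Control replicate 2). Adjusted over all regions, 0 did.

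The edgeR quasi-likelihood test called 0 of 30036 H3K27ac regions, with 1751 at an unadjusted p below 0.05 (814 higher, 937 lower) and a smallest adjusted p of 0.734. DESeq2 called 29 (21 higher, 8 lower), among them Prr35, C1qtnf5, Pla2g2c, Il17re, Zfp94, Cdh23 and Cbs, with adjusted p from 0.000662 to 0.0360. Both Isl1CKO libraries lay outside both Control libraries, on the same side, at 37.5% of regions (5450 above, 5828 below), where chance gives 33.3%. Log2 fold changes of H3K27ac were more positive at higher abundance (Spearman rho = 0.28 across regions), with a median of -0.29 for regions below the median count. Between the Control libraries, replicate 2 over replicate 1, rho was -0.26. The authors' table called 11662 regions, 8750 of them higher (75.03%). With their preset dispersion and TMM factors 5868 were called, 2443 of them higher (41.6%). The count also rested on Control libraries: edgeR called 900 regions (673 higher) without Control replicate 1 and 15 (10 higher) without Control replicate 2. Glp1r passed without Control replicate 1, while Prr35 and C1qtnf5 passed in both cases. Each of these fits left Control with a single library. Without Control replicate 1 that library was Control replicate 2, the one that stood apart from the others.

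The second comparison asked where the repressive mark H3K27me3 differed between the genotypes. Sema5b, Scarf2 and Tnfaip2, among the 4 regions with lower values in Isl1CKO and the smallest p, were wide and strongly marked promoter domains. At Sema5b, an axon guidance semaphorin (chromosome 16, 35354862 to 35368192), H3K27me3 measured 956 ± 56.6 CPM in Control and 543 ± 37.3 in Isl1CKO (SD, n = 2), a log2 fold change of -0.82 (SE 0.14). Scarf2, a scavenger receptor family gene (chromosome 16, 17613397 to 17626790), measured 1177 ± 58.9 and 771 ± 26.4 (SD, n = 2), and Tnfaip2, a gene induced by tumour necrosis factor (chromosome 12, 111408352 to 111415281), measured 397 ± 21.3 and 202 ± 11.9 (SD, n = 2). Their log2 fold changes were -0.61 (SE 0.12) and -0.97 (SE 0.20), and the edgeR adjusted p of these domains was 0.835.

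The 4 regions with higher values and the smallest p were more weakly marked. Acp3, the prostatic acid phosphatase gene, had 0 and 0 counts in Control and 29 and 22 in Isl1CKO in an intron (chromosome 9, 104198741 to 104199043), at least 10.3-fold higher. Ahrr, the repressor of the aryl hydrocarbon receptor, had 0 and 0 against 17 and 39 (chromosome 13, 74437450 to 74438210), at least 11.3-fold higher, and Lpin3, a lipin phosphatase gene, had 0 and 0 against 21 and 32 (chromosome 2, 160721469 to 160722475), at least 10.7-fold higher. Tmem255b measured 93.3 ± 1.47 and 171 ± 23.8 (SD, n = 2) at its promoter (chromosome 8, 13483666 to 13487791). The edgeR adjusted p was 1 for these 4 regions.

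Islet genes that carry H3K27me3 did not pass the test either. The Mafa domain (chromosome 15, 75608703 to 75623320) measured 798 ± 181 CPM in Control and 687 ± 16.1 in Isl1CKO (SD, n = 2), a log2 fold change of -0.22 (SE 0.16) that was 0.03 without Control replicate 1, 0.00 after the loess correction and -0.43 without Control replicate 2. The Sst promoter, at the somatostatin gene (chromosome 16, 23708575 to 23712872), measured 111 ± 7.88 and 131 ± 6.21 (SD, n = 2), a log2 fold change of 0.23 (SE 0.30) that was -0.31 with the authors' implied sizes. Pdx1 had a log2 fold change of 0.34 (SE 0.59), which was -0.28 with those sizes, -0.09 without Control replicate 2 and 0.94 without Control replicate 1. A distal Nkx6-1 region had one of -1.65 (SE 0.82), which was 0.89 without Control replicate 2 and -2.51 without Control replicate 1. The single H3K27me3 region at Isl1, a distal region with 5 and 15 counts in Control and 9 and 71 in Isl1CKO, had one of 1.34 (SE 1.16), which was -0.78 without Isl1CKO replicate 2.

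Among lists, 37 of 47 Polycomb-regulated developmental genes measured lower and 10 higher, with a median log2 fold change of -0.17 (camera adjusted p = 0.522). In 24 of these genes both Isl1CKO libraries lay below both Control libraries, and in 1 both lay above. The median of the list was 0.03 after the loess correction. Across scalings, the median of all H3K27me3 regions was 0.05 with TMM, 0.16 with library totals and -0.51 with the authors' implied sizes. Other settings changed the direction that camera gave in 15 of the 19 lists. Barx1, a homeobox gene of stomach mesenchyme (chromosome 13, 48809008 to 48828140), measured 1557 ± 20.3 and 1148 ± 74.4 (SD, n = 2). Barx1 was among the genes that passed when adjusted over the list alone, with edgeR adjusted p of 0.0421 in the Polycomb list and 0.0143 in the mesenchymal list. Adjusted over all regions, 0 list members passed. All 6 measured genes of hormone secretion measured higher with TMM (median 0.57, camera adjusted p = 0.522), and this list passed camera without Control replicate 1, at an adjusted p of 0.0491. With all 4 libraries and an estimated correlation its adjusted p was 0.964 (unadjusted p = 0.324), and its median was 3.61 without Control replicate 1 and 0.03 without Control replicate 2. The 8 mesenchymal markers (7 lower) had a median of -0.30, the 12 neuronal genes (10 lower) one of -0.08, the 8 endocrine progenitor genes (7 lower) one of -0.20 and the 20 beta-disallowed genes (14 lower) one of -0.29. Prph, the peripherin gene of neurons, stood at -0.47 (SE 0.18), or -0.29 without Control replicate 1, and Pdgfra, a growth factor receptor of mesenchyme, at -0.42 (SE 0.14). The medians of the 9 beta, 8 alpha, 6 delta and 5 PP and epsilon genes were -0.21, -0.11, -0.03 and -0.29, with 0.25 for beta genes without Control replicate 2 and 0.12 for PP and epsilon genes without Control replicate 1. Those of 16 islet transcription factors, 8 gut endocrine, 4 cell cycle and 2 stress genes were -0.03, -0.04, -0.08 and -0.42, with 1.02 for stress genes without Control replicate 2. Those of 5 acinar, 6 ductal, 7 endothelial, 5 immune and 3 glial markers were -0.13, 0.36, -0.02, 0.30 and 0.13. No H3K27me3 list passed camera with an estimated correlation (smallest adjusted p 0.964).

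Log2 fold changes of H3K27me3 were more negative at higher abundance (Spearman rho = -0.24 across regions, which are not independent replicates). Between the Control libraries, replicate 2 over replicate 1, rho was -0.01. The 1581 regions of at least 5000 bp had a median of -0.16 (quartiles -0.33 and 0.02), and 1148 of them (72.6%) measured lower in Isl1CKO. After the loess correction this median was 0.02, with 755 (47.8%) lower.

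The edgeR quasi-likelihood test called 0 of 19434 H3K27me3 regions, with 843 at an unadjusted p below 0.05 (263 higher, 580 lower) and a smallest adjusted p of 0.835. DESeq2 called 123 (3 higher, 120 lower), among them Sema5b, Scarf2, Tnfaip2 and Barx1, with adjusted p from 1.84e-08 to 0.000423. Of the 120 lower, 80 were promoters and 64 were at least 5000 bp wide. All 64 wide regions stayed lower after the loess correction, with a median of -0.37, but they were picked for low values. The genotypes did not overlap at 35.4% of regions (3629 with Isl1CKO above, 3242 below), where chance gives 33.3%. The authors' table called 7791 regions, 1841 of them higher (23.6%), and their preset dispersion with TMM factors called 5044, 2900 of them higher (57.5%).

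**Figure D1:**
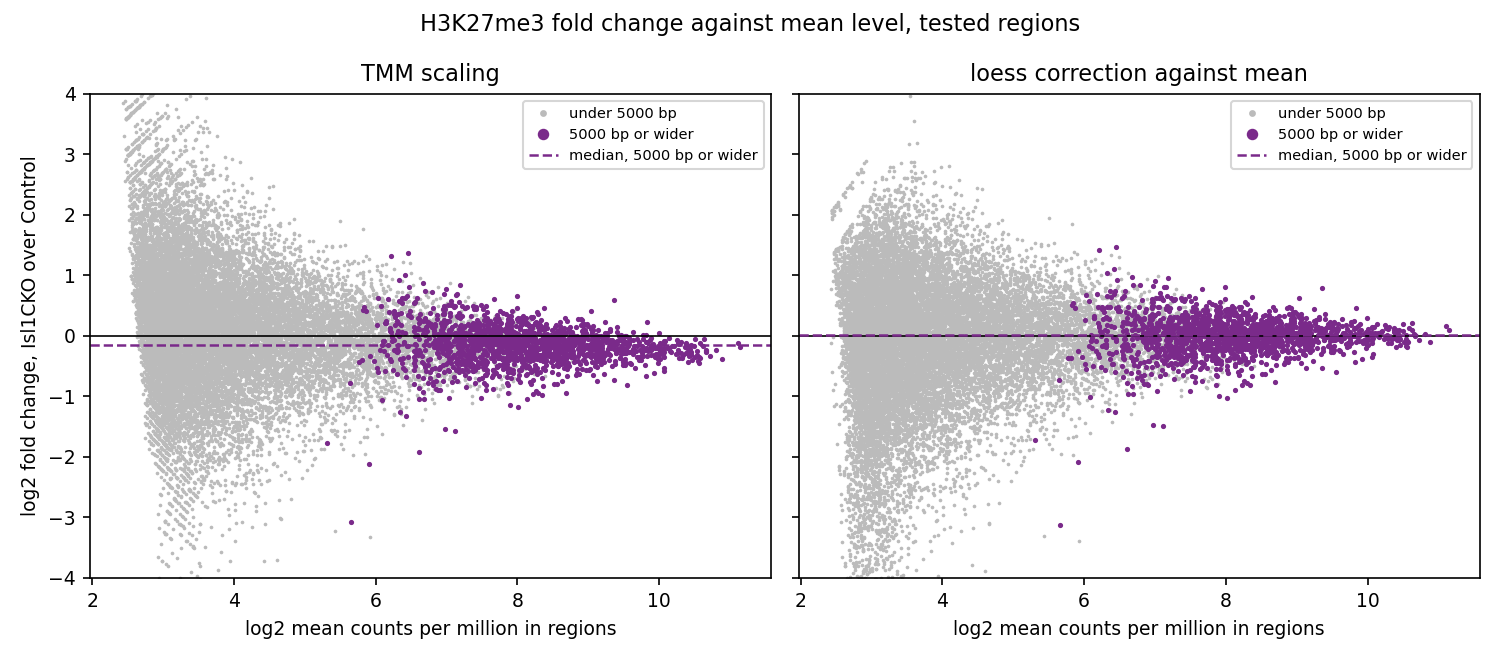
Log2 fold change of H3K27me3, Isl1CKO over Control, against log2 mean CPM for each tested region, with TMM factors and after the loess correction. Regions of at least 5000 bp are in purple, and the dashed line is their median, -0.16 before and 0.02 after the correction.

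The third comparison set the 2 marks against each other at promoters of the same genes. Across 1366 genes with both, the log2 fold changes correlated weakly and negatively (Spearman rho = -0.16, Pearson r = -0.12, permutation p = 0.0001 for both, the smallest that 10000 permutations can give). Genes are not independent replicates. H3K27ac measured higher with H3K27me3 lower at 428 genes, and lower with H3K27me3 higher at 264, while both measured lower at 524 and higher at 150. At Mafa, for example, the promoter log2 fold changes were -1.70 for H3K27ac and -0.22 for H3K27me3, and at Mnx1, a homeobox gene of beta cells and motor neurons, they were -2.32 (SE 0.83) and -0.42 (SE 0.19), although the first was -0.48 without Control replicate 2. Without Control replicate 2 of H3K27ac, rho was -0.12 and Pearson r -0.08, and after the loess correction of both marks, whose fold changes trend with abundance in opposite directions, rho was -0.12 and r -0.10. Fisher's exact test had no calls of edgeR to work on. With the authors' calls, 203 genes were higher for H3K27ac and lower for H3K27me3 against 183 expected, an odds ratio of 1.36 (Fisher's exact p = 0.0150, adjusted p = 0.0599 over 4 combinations). None of the 4 combinations passed after adjustment, with 64 genes lower for both against 64.8 expected.

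The fourth comparison described the promoter windows with ISL1 values in Control cells at E14.5 and P9. No background library was among the samples, so a window with a value is not a tested binding site. The stated aim of these libraries was to find direct targets of ISL1. The 22332 promoter windows, 19583 of them 6000 bp wide, had a value of at least 1 at 8426 windows at E14.5 (37.7%) and at 1978 at P9 (8.86%). Both stages had a value at 1043 windows, where independent sets would share 746, and 52.7% of the P9 windows were also positive at E14.5. The E14.5 values summed to 16668 and the P9 values to 2255. Values of at least 2 stood at 4097 windows at E14.5 and at 207 at P9. Thinned to the P9 sum, E14.5 gave 1968 positive windows (1927 to 2012 over 100 draws) against the 1978 at P9. P9 had 1 library and E14.5 a pooled column, so no stage difference was tested, and the unit of the values is not stated.

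Islet regulators were among the windows with ISL1 at E14.5. The window of Isl1 itself (chromosome 13, 116443226 to 116449225) had a value of 9 at E14.5 and 0 at P9. Nkx2-2, Insm1 and Tshz1, transcription factors of islet development, had 7, 7 and 7 at E14.5 and 1, 0 and 0 at P9. Mafa (chromosome 15, 75617078 to 75623077) and Pax6, an islet and eye factor, both had 6 and 0, Nkx6-1 had 5 and 1, and Pdx1 had 4 and 0. Neurod1 and Foxa2, regulators of endocrine and endodermal genes, had 2 at both stages. Fev, an ETS factor of endocrine progenitors and serotonin neurons (chromosome 1, 74921579 to 74927578), had 14 and 2. Hormone genes had few or no values: Ins1, Ins2, Gcg and Iapp had 0 at both stages, as had Ucn3 and Glp1r, while Sst had 1 and 0 and Ppy 0 and 1. The highest E14.5 value was at Hinfp, a histone gene regulator (chromosome 9, 44213969 to 44219968), followed by Cyb5r3 with 66 and Bcar3 with 46. At P9 these had 0, 0 and 2. The highest P9 values, chosen after they were seen, were 8 at the cytokine receptor gene Osmr and 7 at Nodal, each with 1 at E14.5.

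Of the 19 lists, islet transcription factors had ISL1 most often. They had a value at 27 of 28 windows at E14.5, against a mean of 17.1 in random lists matched on both marks and window width (permutation p = 0.0002, the smallest possible, adjusted p = 0.0019). At P9 they had it at 13 of 28, against 3.85 (adjusted permutation p = 0.0038). Polycomb-regulated developmental genes had it at 47 of 56 windows at E14.5, against 25.6 (adjusted permutation p = 0.0019), and at 15 of 56 at P9, against 8.56 (adjusted permutation p = 0.315). No other list passed this comparison at either stage. Both marks were measured at P9 alone, so at E14.5 the lists were matched on marks of the later stage. At E14.5, beta identity genes had it at 12 of 21 windows against 10.7, alpha genes at 13 of 18 against 8.45, and endocrine progenitor genes at 15 of 18 against 11.4.

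**Figure D2:**
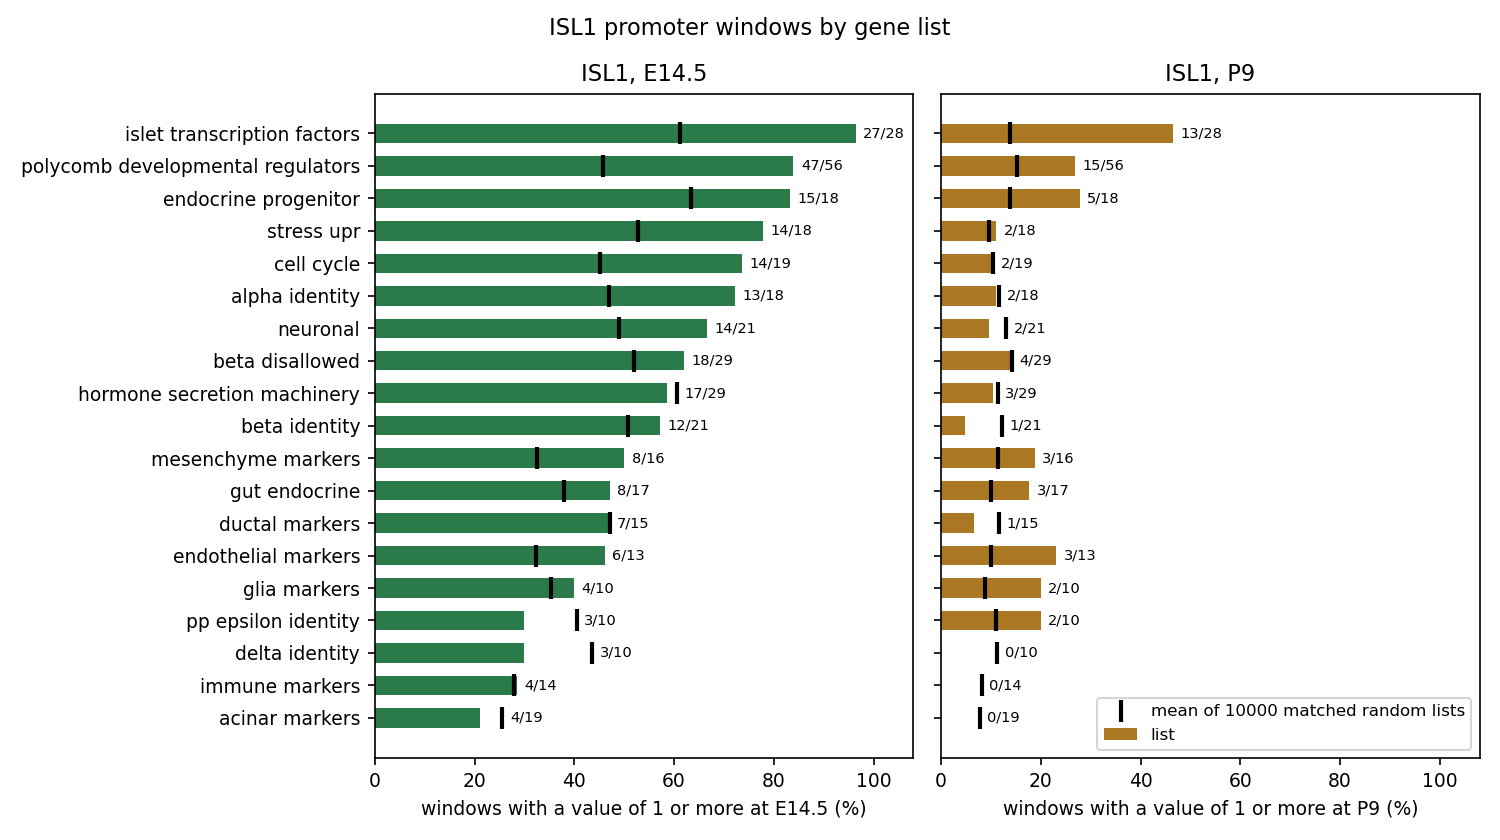
Percent of promoter windows with an ISL1 value of at least 1 per gene list, at E14.5 (2 pooled libraries) and P9 (1 library), with a tick for the mean of 10000 random lists matched on H3K27ac, H3K27me3 and window width. Islet transcription factors stand at 96.4% at E14.5 and 46.4% at P9, against 61.2% and 13.7% in matched lists.

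The fifth comparison asked whether histone regions that differed between genotypes overlapped ISL1 windows. With 0 called regions, it used those at an unadjusted p below 0.05, among the 12612 H3K27ac and 4795 H3K27me3 regions that overlap a window. Over all tested regions, 5.83% for H3K27ac and 4.34% for H3K27me3 reached this level, where 5% are expected with no change. Most of the regions at this level over all tested can thus be chance. Among overlapping regions, H3K27ac had 274 lower and 393 higher, and H3K27me3 had 311 lower and 24 higher. The share over all tested regions does not describe each of these directions. Because regions are not independent replicates, the Fisher's exact p values of this comparison describe association across regions only. H3K27me3 regions with lower values in Isl1CKO had ISL1 at 266 of 311 (85.5%), against 62.8% of 4460 other regions, an odds ratio of 3.49 (Fisher's exact adjusted p = 3.09e-16). Scarf2, with an ISL1 value of 2 at E14.5, and Sema5b, with 2 at P9, were among them. Wide regions had ISL1 more often: within the widest tertile the shares were 91.7% and 77.6% (odds ratio 3.18, adjusted p = 1.50e-06), and no difference passed in the other tertiles of width. With the replicate block and with the authors' calls, the middle tertile of width also passed (adjusted p = 0.0383 and 0.00804). By mean count, the highest tertile (91.6% and 77.3%, adjusted p = 1.50e-06) and the middle tertile (71.8% and 57.3%, adjusted p = 0.0429) passed, and the lowest did not. With the authors' calls the odds ratio was 1.51, and by gene rather than overlap it was 2.31. Lower H3K27me3 values went with higher abundance (rho = -0.24) and the median of wide regions was 0.02 after the loess correction, so this overlap does not separate ISL1 from that trend. H3K27me3 regions with higher values had ISL1 at 10 of 24 (41.7%, odds ratio 0.422, adjusted p = 0.104). H3K27ac regions with lower values had ISL1 at 161 of 274 (58.8%), against 68.7% of 11945 others (odds ratio 0.649, adjusted p = 0.00396). Those with higher values had it at 294 of 393 (74.8%, odds ratio 1.35, adjusted p = 0.0484). Fold changes of H3K27ac trend with abundance, and neither of these differences passed within any tertile of mean count or width, and most of the positive windows were from E14.5. Mafa had a value at its window at E14.5 and lower H3K27ac values, while Ucn3 and Glp1r had 0 at both stages.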

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

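Alternatives chosen only after the data were seen were the authors' implied library sizes and preset dispersion, the loess correction, counts summed per gene, the low-count filter applied again, the thinned ISL1 values, the tests of ISL1 overlap with their tertiles of width, and the H3K27ac against H3K27me3 correlation without Control replicate 2. The edgeR count of 0 called regions held for both marks with DESeq2 size factors in edgeR, library totals, no filter, the replicate block (0 and 0), promoters alone, the loess correction, sums per gene and an absolute log2 fold change of at least 1. In edgeR, 1751 H3K27ac and 843 H3K27me3 regions had an unadjusted p below 0.05, and by DESeq2 29 and 123 regions were called. The replicate numbers did not pair the libraries (the difference between the Control replicates correlated with that between the Isl1CKO replicates at 0.048 and -0.014 across regions). Leaving out each library in turn gave 0 to 900 H3K27ac calls and 0 for H3K27me3. The 900 came without Control replicate 1 and 15 came without Control replicate 2. With the filter applied again, these became 2189 and 15 for H3K27ac, and 10 for H3K27me3 without Control replicate 1. A genotype left with 1 library was assumed to vary like the other. The authors' implied sizes gave 3 and 0 calls, the preset dispersion 5868 and 5044, and the calls in the authors' table were 11662 and 7791. Apart from the preset dispersion and the implied library sizes, weighed with the other observations, the cause of these shifts was not tested.

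Of 171 list values for H3K27ac, all stayed on the same side of the threshold, with 26 changes of the camera direction in 11 lists. For H3K27me3 170 of 171 did, with 29 changes of the camera direction in 15 lists, and leaving out each library gave 0 to 1 lists past it. Of 919 values for 52 named H3K27ac regions, 795 stayed and 124 passed in 43 regions, with 20 changes of sign in 6. Of 814 for 46 H3K27me3 regions, 759 stayed and 55 passed in 35, with 44 changes of sign in 15. Values past the threshold came from the authors' table (66), the preset dispersion (62), DESeq2 (12), the implied sizes (1), and from leaving out Control replicate 1 (17, or 18 with the filter applied again) or Control replicate 2 (2 and 2). ISL1 windows above the median of positive values numbered 4097 at E14.5 and 207 at P9, with 98 at both, and E14.5 thinned to the P9 sum gave 1968. For ISL1 overlap of lower H3K27ac regions, P9 windows alone gave an odds ratio of 0.770 and the same gene one of 0.816, neither past the threshold. For higher H3K27ac regions it was 1.25 with E14.5 windows alone and 0.998, no difference, with P9 windows alone (11.96% against 11.98%, Fisher's exact p = 1). For higher H3K27me3 regions it was 0.422, not past the threshold, as were 0.482 with the replicate block, 0.447 with P9 windows alone and 0.780 above the median value. It was 0.467 within 5 kb, 0.460 for the same gene, 0.370 with E14.5 windows alone and 0.613 with the authors' calls, all 4 past the threshold. The cause of these shifts was not tested. The alternatives for normalized values (pseudocount and filter) had no object in a count table, and a larger share of overlap between ISL1 sites had none in windows shared by both stages, so these were not run. In simulations at the observed depth and dispersions, the test recovered 0% and 2% of 2-fold changes for H3K27ac and H3K27me3. It recovered 18% and 28% of 4-fold changes, and 72% and 48% of 16-fold changes. The 0 calls therefore do not exclude differences of these sizes. Depth and the number of libraries were not varied.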

Other observations

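Tests chosen only after the result was seen were those of the preset dispersion, of signal over background, of all wide domains as a set, and, over the beta identity genes, of Control replicate 2 alone, of the trend with abundance and of fewer beta cells. ISL1 windows at E14.5 were more frequent at promoters that carried H3K27ac or H3K27me3 at P9. At E14.5, 22.7% of windows without an H3K27ac promoter region had an ISL1 value, against 47.5%, 61.7% and 77.4% from the lowest to the highest tertile of promoter H3K27ac. At P9 the shares were 7.46%, 11.6%, 9.10% and 12.7%, without a rise over the tertiles. Windows with an H3K27me3 promoter region had ISL1 at 56.2%, against 34.8% without, and at P9 at 17.7% against 7.46%. Promoters with both marks stood at 67.0% and those with neither at 18.1% at E14.5. Wider windows had ISL1 more often than windows of 6000 bp, at 60.8% against 34.5%. These shares were not tested.

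The other gene lists did not pass against matched lists at E14.5. Cell cycle genes had it at 14 of 19 windows against a matched mean of 8.59 (adjusted permutation p = 0.0811), stress genes at 14 of 18 against 9.52 (0.126), and neuronal genes at 14 of 21 against 10.3. Hormone secretion genes had it at 17 of 29 windows against 17.6, beta-disallowed genes at 18 of 29 against 15.1, and gut endocrine genes at 8 of 17 against 6.46. PP and epsilon genes had it at 3 of 10 windows and delta genes at 3 of 10, against 4.05 and 4.35. Markers of other cell types had it at 4 of 19 acinar, 7 of 15 ductal, 8 of 16 mesenchymal, 6 of 13 endothelial, 4 of 10 glial and 4 of 14 immune windows. Among single genes, Lmx1a had a value of 6 at E14.5 and 1 at P9, the alpha cell factor Irx2 had 6 and 0, and Abcc8 had 3 and 0.

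The first pattern is the contrast between 11662 H3K27ac and 7791 H3K27me3 calls in the authors' table and 0 in the edgeR quasi-likelihood test. The authors' implied library sizes alone are excluded as the cause of the number of calls, since with them that test called 3 and 0 regions. A candidate explanation is the likelihood ratio test with the preset dispersion, a change of test and of dispersion that were not separated. With TMM factors it gave 50.3% as many H3K27ac calls and 64.7% as many H3K27me3 calls as the table. With the implied sizes as well, 99.98% and 99.99% of regions had the same call as in the table, though these settings were fitted to that table. The direction followed the sizes. In the quasi-likelihood test, the implied sizes gave medians of 0.61 and -0.51 over all regions, and TMM gave -0.03 and 0.05. With TMM and the preset dispersion 41.6% and 57.5% of calls were higher, against 75.03% and 23.6% in the table. Tested for genotype with 2 libraries each, the quasi-likelihood test called 0 regions in both marks and DESeq2 called 29 and 123. These results do not decide which of the authors' calls follow from the genotype.

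The second pattern is the lower H3K27me3 of wide domains in Isl1CKO. For all 1581 wide domains, whose median went from -0.16 to 0.0153 after the loess correction, a trend with abundance could account for the shift. The correction was fitted over all tested regions, and the wide domains among them held 56.7% and 56.9% of counts in the Control libraries. Such a fit can bring these domains near 0 in either case, so this median does not separate a trend between libraries from a loss of the mark. The median of the 4 lower domains with the smallest p, Sema5b, Scarf2 and Tnfaip2 among them, went from -0.77 to -0.56, but these were picked for low values, so the trend as the whole cause stays open for them. Lower signal over background in the Isl1CKO libraries may be its source, since regions with counts below the median had a median of 0.30 and the strongest decile held 62.8% and 62.4% of counts in Isl1CKO against 65.9% and 65.9% in Control. A loss of the mark at strong domains in Isl1CKO cells would look alike in data scaled to totals and stays open, as a hypothesis not tested here.

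The third pattern is the lower H3K27ac over 18 beta identity genes, a list that did not pass camera, with a median log2 fold change of -0.34 (quartiles -1.03 and -0.06). Control replicate 2 alone stays open as its cause, since without it the median was -0.23 with an upper quartile of 0.03. After the loess correction the median was -0.45 (quartiles -1.03 and -0.22), further from 0, with 15 genes lower and 3 higher. These values argue against the trend with abundance as the cause over these 18 genes. The camera adjusted p was 0.213 before the correction and 0.0996 after it, so the list passed in neither case. The lowest listed promoters, named after their values were seen, were those of Ucn3, Mafa, Pcsk1 and Glp1r at -2.13, -1.70, -1.44 and -1.22, and the 5 regions of Ucn3, Mafa and Glp1r had a median of -1.72 after the loess correction, which excludes nothing in regions picked for low values. Fewer beta cells in the Isl1CKO pools, which would raise alpha identity genes (median 0.0554, 5 lower and 8 higher), cannot be told apart from an effect of Isl1 loss within beta cells, which is a hypothesis not tested here.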
